A study of Arabidopsis thaliana with 21 samples.

How the data were processed

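RNA was profiled in leaves of Arabidopsis thaliana Col-0 plants grown, per the labels, under short days. The series holds 21 libraries: 9 small RNA libraries (AWF, LSW and lysate, 3 each) made with the RealSeq-AC kit, and 12 RNA-seq libraries (AWF, LSW, ribodepleted lysate and not ribodepleted lysate, 3 each) made with a directional NEBNext kit. Lysate RNA was extracted with TRIzol. How AWF and LSW were collected, and whether they were ribodepleted, is not given in the sources used here.

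The small RNA files hold whole-number read counts per miRNA as deposited, made by the authors without normalization, with identical mature sequences merged and miRNAs without a count left unlisted. The submitters' processing notes name cutadapt 1.16 for trimming, FastQC, Bowtie2, HISAT2 and StringTie on the TAIR10 genome build; versions of FastQC, Bowtie2 and HISAT2 are not given in the sources used here. The RNA-seq files are StringTie transcript tables with coverage, FPKM and TPM per reference transcript, and per the file headers the authors made them with StringTie 2.1.4 restricted to reference transcripts. The strand option was not set, so reads of overlapping or antisense genes are uncertain. TPM in each file is scaled over all 41671 listed transcripts of 33610 genes, and all 279 chloroplast and mitochondrial genes (133 and 146) were at 0 in every library, so organelle RNA is not analysed here. The file of LSW replicate 3 holds 0 for every transcript and was left out, and its header names another kind of alignment than the other 11 do. AWF RNA-seq files carry other replicate numbers than their labels, and the labels were used. AWF and lysate RNA-seq libraries of the same label number therefore may not belong together, and a replicate block says little about AWF against lysate there.

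Transcript values were summed per gene. Of the 33610 genes, 28932 matched the gene table, which gave symbols, classes and coordinates, and 4678 did not. Classes were nuclear protein-coding (26709 genes), transfer RNA (623), miRNA precursor (178), small nucleolar RNA (71), small nuclear RNA (13), nuclear rRNA (4), other non-coding RNA and pseudogenes (1333) and genes outside the table (4399). The open reading frame AT2G01021 inside the rRNA repeat was set apart from protein-coding genes after its values were seen, a departure from the first plan. Because rRNA took most of TPM, TPM of nuclear protein-coding genes was rescaled to a total of 1000000 per library (rescaled TPM). Genes with at least 1 rescaled TPM in at least 3 libraries were tested (15504), as log2(rescaled TPM + 1), with limma-trend (limma 3.58.1 in R 4.3.3) over 6 contrasts. Fragment numbers were estimated from coverage times length in units of 220 bases. Expected fragments are those a wash library of that depth would hold at the lysate level, and 1368 bases is the median gene length used for the value of 1 fragment.

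MiRNA counts were tested with the edgeR 4.0.16 quasi-likelihood test after TMM scaling and its expression filter (142 of 286 miRNAs) over 3 contrasts. The values of CPM are scaled by TMM. All tests were two-sided, with calls at an adjusted p under 0.05. P values of single genes and miRNAs were Benjamini-Hochberg adjusted within each contrast. Those of list tests were adjusted over all lists and contrasts of a setting together. Class shares (27 tests) and numbers of detected genes were compared by exact permutation tests, for which 3 libraries against 3 give at least p = 0.1. The labels do not say that replicates are separate plants, so p values measure the spread between samples. Where a group was at 0 counts, the bound ("at least") set the pooled level of the other group against 3 counts over the group at 0. It leaves out the error and spread of the other group, so single libraries may lie below it. With 1 to 3 counts the ratio has an exact 95% counting interval. Intervals and floors cover counting error only.

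The groups, contrasts, gene lists, miRNA lists, main settings and 29 of the alternative settings were chosen before the data were examined; 13 settings were added after seeing them. The 14 gene lists were light harvesting and photosystem, Calvin cycle, guard cell, epidermis and cuticle, trichome, vascular, salicylate and immune, jasmonate and wounding, touch and rapid response, cytosolic ribosomal proteins, circadian, reference, pollen and root. The 7 miRNA lists were copper, phosphate and sulfate, auxin pathway, growth and phase, small RNA pathway, secondary siRNA trigger and Brassicaceae young. Gene lists with measured members were tested in 3 contrasts (39 tests) with camera, at a preset correlation of 0.01 and with an estimated correlation, and with fry. MiRNA lists were tested with fry. Fry tests whether members move one way on balance, not whether they differ from other genes.

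Genes named were, per contrast, up to 8 with the largest and 8 with the smallest log2 fold change among called genes with a mean of at least 10 rescaled TPM in the higher group and no overlap between groups. Named miRNAs were 6 in each direction per contrast and the 4 most abundant of each fraction. For each list up to 4 called members were named, or the 2 most abundant where 0 were called. Other named genes were chosen after their values were seen.

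Alternatives were TPM as deposited, quantile normalization, other pseudocounts (0.1, 5 and, added, 300), no filter and a stricter filter (10 rescaled TPM), edgeR on estimated reads, DESeq2 1.42.0, DESeq2 size factors or library size in edgeR, thinning to the smallest library (100 draws for miRNAs, 20 for mRNA), the replicate number as a block, the compared groups alone, and leaving out each library in turn. FPKM shares equal TPM shares by construction and test nothing. Deviations from the group mean correlated between same-numbered libraries of the lysate pair alone (0.265 to 0.517, against a threshold of 0.1 and -0.193 to 0.0835 for other pairs of groups). Fold changes that share a lysate were compared with 20 simulations of unchanged groups, and list medians with 10000 random lists matched for the mean log2 level over all RNA-seq libraries with values. The tests were tested on simulated data at the depths of these libraries: for miRNAs 95% of 16-fold changes and 10% of 4-fold changes between LSW and AWF were found, with 1 false call, and for mRNA limma found 22 of 100 genes raised 16-fold in AWF and 0 of 100 raised 4-fold. At 16-fold, limma with a pseudocount of 300 found 1 of 100 and edgeR 2 of 86, so a call lost in these alternatives is weak evidence against it. Tables were handled in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots drawn with matplotlib 3.10.9.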

Results

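The series profiled RNA found outside the cells of Arabidopsis thaliana leaves of the accession Col-0. Apoplastic washing fluid (AWF) is liquid recovered from the spaces between leaf cells, leaf surface wash (LSW) is liquid rinsed from the outside of leaves, and cell lysate is RNA extracted from whole leaf tissue. The comparisons ask which RNAs each wash held, how the washes differed from each other and how each differed from the lysate. Of the 21 libraries, 9 were small RNA libraries in 3 groups of 3 (AWF, LSW and lysate) and 12 were RNA-seq libraries in 4 groups of 3 (AWF, LSW, and lysate with and without removal of ribosomal RNA, here ribodepleted and not ribodepleted). The labels do not say whether the washes were ribodepleted, so both lysates served as references, with the not ribodepleted lysate as the main one.

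Depth differed widely between fractions. The small RNA files listed 286 miRNAs, with total counts of 72362, 6967 and 7008 in AWF replicates 1, 2 and 3, of 258712, 233065 and 14000 in LSW, and of 992999, 1252371 and 1681041 in lysate. A count of 0 therefore allowed up to 41.5, 431 and 428 counts per 1000000 (CPM) in the AWF libraries, 11.6, 12.9 and 214 in LSW, and 3.02, 2.40 and 1.78 in lysate, taking 3 counts of the library total as the limit. The RNA-seq files covered 1677.4, 1635.64 and 1361.61 megabases in AWF, 496.145 and 3726.73 in LSW replicates 1 and 2, 1752.27, 210.73 and 1172.7 in not ribodepleted lysate, and 717.839, 490.836 and 447.742 in ribodepleted lysate. LSW replicate 3 was listed at 0 for every transcript, which left 2 LSW libraries with values. Little of the AWF coverage fell on nuclear mRNA, which received the equivalent of 4811, 2969 and 2249 fragments, against 344491, 14765 and 153839 in not ribodepleted lysate and 18277 in LSW replicate 1. On a gene of median length, 1 fragment was worth 247, 386 and 473 rescaled TPM in the 3 AWF libraries and 56.2 in LSW replicate 1.

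Nuclear mRNA made up far less of AWF RNA than of lysate RNA. Its share of TPM was 0.0341% ± 0.0123 (SD, n = 3) in AWF, 2.09% ± 0.759 in not ribodepleted lysate and 6.47% ± 1.62 in ribodepleted lysate, a share 61.3-fold and 189.8-fold smaller in AWF (62.8-fold and 658-fold by covered bases). The larger gaps to ribodepleted lysate take in the removal of rRNA from that lysate. Small nuclear RNA, the RNA part of the spliceosome, fell in the same direction, from 0.2235% ± 0.0361 in not ribodepleted lysate to 0.00587% ± 0.00201 in AWF. Its most abundant locus, U1.5 (AT1G08115, chromosome 1, 2538076 to 2538237), had 51.6, 81.1 and 42.1 TPM in AWF and 2491, 1789 and 1950 TPM in not ribodepleted lysate. Small nucleolar RNA, which guides modification of rRNA in the nucleolus, was 9.07e-05% of TPM in AWF and 0.0135% ± 0.00204 in that lysate, and other non-coding RNA 0.0392% ± 0.0195 and 0.411% ± 0.0681. AT1G15405 (chromosome 1, 5297875 to 5298166) carried most of the other non-coding value. Transfer RNA and miRNA precursors were listed at 0 in all 3 AWF libraries. For each of these classes the AWF libraries lay below all libraries of both lysates, with an exact two-sided permutation p of 0.1 (adjusted 0.1125 over 27 tests), the smallest value that 3 libraries against 3 can give.

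Nuclear ribosomal RNA dominated every RNA-seq library. It held 87.3% ± 3.74 (SD, n = 3) of TPM in AWF, 82.8% ± 1.24 in not ribodepleted lysate and 88.9% ± 1.29 in ribodepleted lysate, with overlap between AWF and each lysate (exact permutation p = 0.2 and 0.6, adjusted 0.216 and 0.623, where 0.1 is the smallest possible). As a share of covered bases, which does not divide by length, it held 98.8% ± 0.462 in AWF, 95.4% ± 1.32 in not ribodepleted lysate and 66.04% ± 10.8 in ribodepleted lysate. All AWF libraries then lay above all libraries of both lysates (exact permutation p = 0.1, adjusted 0.108, n = 3). The 18S copies AT2G01010 (chromosome 2, 3706 to 5513) and AT3G41768 (chromosome 3, 14197677 to 14199484) and the 5.8S copies AT2G01020 (chromosome 2, 5782 to 5945) and AT3G41979 (chromosome 3, 14199753 to 14199916) carried these values. The 18S copy AT3G41768 alone took 38.3%, 35.0% and 30.2% of TPM in the AWF libraries. It took 26.9%, 34.3% and 30.2% in not ribodepleted lysate and 0.899%, 3.44% and 0.776% in ribodepleted lysate. LSW replicates 1 and 2 had 41.7% and 2.42%. These values argue against AWF having been ribodepleted in the way of that lysate. The LSW libraries differ too much to tell. Copies of the repeat are near-identical, so the division between loci is uncertain. A short open reading frame inside the repeat, AT2G01021 (chromosome 2, 6571 to 6672), is annotated as protein-coding and was counted apart from mRNA. It took 12.6% ± 3.76 of TPM in AWF, 14.4% ± 1.95 in not ribodepleted lysate and 2.25% ± 0.603 in ribodepleted lysate. The rRNA shares of TPM above leave it out. All other classes lay lower in each AWF library than in every lysate library. Thus rRNA and this reading frame together held more of TPM in AWF than in either lysate. In ribodepleted lysate the 5.8S copies AT2G01020 (43.0%, 41.9% and 44.9% of TPM) and AT3G41979 (43.9%, 42.5% and 41.6%) carried most of the rRNA value.

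The LSW libraries with values did not resemble each other. In LSW replicate 1, nuclear mRNA held 0.745% of TPM, 2.80-fold less than the mean of not ribodepleted lysate and 21.8-fold more than the AWF mean. There, small nuclear RNA held 0.0162%, small nucleolar RNA 0.000692%, other non-coding RNA 0.229% and rRNA 81.7%. In LSW replicate 2, rRNA held 99.9% of TPM, the single 5.8S locus AT3G41979 took 72.7%, and mRNA held 0.0464%. Of that mRNA value, 97.9% fell on 67 genes of the mitochondrial DNA insertion in chromosome 2, against 0.847% in LSW replicate 1. Mitochondrial genes were listed at 0 in every library, so these reads cannot be told from mitochondrial RNA. The correlation between these libraries across genes was 0.174, so LSW mRNA values are given below for replicate 1 as a single library, and tests of LSW mRNA rest on a pair of unlike libraries.

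**Figure D1:**
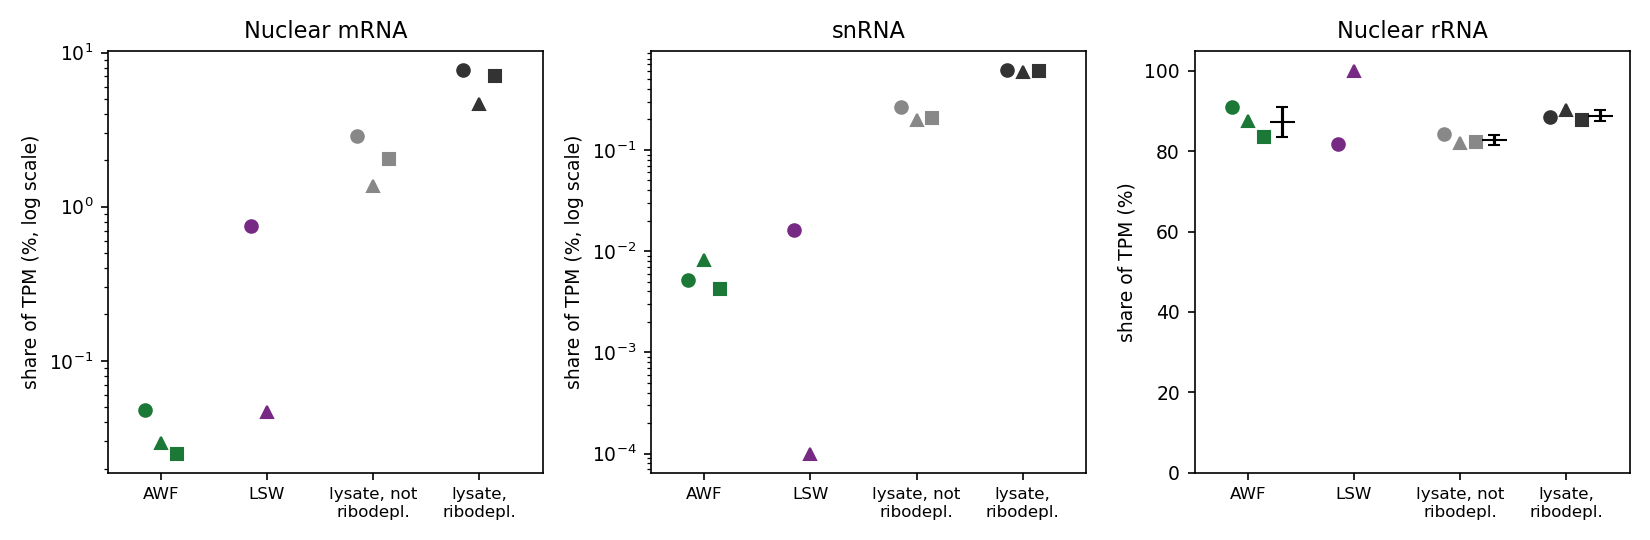
Share of deposited TPM (%) held by nuclear mRNA, small nuclear RNA (both on log axes) and nuclear rRNA in each RNA-seq library; circles, triangles and squares are replicates 1, 2 and 3, and black bars in the rRNA panel are means ± SD of 3 libraries. AWF libraries lie below both lysates for mRNA and small nuclear RNA, while rRNA lies between 81.7% and 99.9% in LSW and averages 87.3% in AWF. The rRNA panel leaves out the reading frame AT2G01021 of the rRNA repeat.

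Fewer protein-coding genes were seen in AWF than in lysate. Genes at or above 1 rescaled TPM numbered 1521, 1091 and 840 in AWF, 14365, 3667 and 11858 in not ribodepleted lysate, 16947, 14287 and 16189 in ribodepleted lysate and 4473 in LSW replicate 1. The AWF mean was lower than that of not ribodepleted lysate by a difference of -8813 genes and than that of ribodepleted lysate by -14657 (exact permutation p = 0.1, adjusted 0.15, n = 3 against 3, for both). Every library was also thinned to 2293 mRNA fragments, an alternative chosen after seeing the data. The mean was then 913 ± 110 genes (SD, n = 3) in AWF, 1422 ± 122 in not ribodepleted lysate and 1509 ± 52.8 in ribodepleted lysate, and LSW replicate 1 gave 1468. The difference between AWF and not ribodepleted lysate was then -509 genes (exact permutation p = 0.1, adjusted 0.15, n = 3).

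Single genes reached high rescaled TPM in AWF, on few fragments, and were scarce in lysate. LOX4 (AT1G72520, chromosome 1, 27308515 to 27312754), a lipoxygenase that starts jasmonate synthesis, averaged 3898 ± 2797 rescaled TPM (SD, n = 3) in AWF and 17.0 in not ribodepleted lysate. Its log2 fold change on the log2(rescaled TPM + 1) scale was 9.74 ± 1.77 (SE, limma adjusted p = 0.00399). AOC3, an allene oxide cyclase of the same pathway, averaged 1227 ± 390 and 4.93 (8.89 ± 1.85, limma adjusted p = 0.00848). The chaperone HSP90.1 averaged 1907 ± 1246 and 4.73 (9.34 ± 1.35, limma adjusted p = 0.00238), and PUB23, an E3 ubiquitin ligase that limits drought and immune signalling, 2013 ± 937 and 6.77 (8.56 ± 1.84, limma adjusted p = 0.0102). DAR6 averaged 613 ± 310 in AWF and was listed at 0 in all 3 not ribodepleted lysate libraries (limma adjusted p = 0.00238). Over the 3 AWF libraries together, LOX4 had an estimated 64.9 fragments, HSP90.1 31.2, PUB23 18.8, AOC3 7.9 and DAR6 7. The far deeper not ribodepleted lysate had 38.3, 8.7, 6.6, 3.7 and 0.

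In all, limma called 31 genes higher and 2004 lower in AWF than in not ribodepleted lysate among 15504 tested. The other genes named by the fixed rule as highest were AT1G15010 (log2 fold change 10.16 ± 1.24, limma adjusted p = 0.00238), AT1G56660 (8.52 ± 1.93, limma adjusted p = 0.0138) and AT2G42760 (8.37 ± 1.94, limma adjusted p = 0.0154). They had an estimated 8.6, 39.4 and 8.6 fragments in AWF and 1, 18.7 and 11.4 in the far deeper not ribodepleted lysate. The 8 highest named genes all passed an edgeR test on estimated reads as well, and all but LOX4 (limma adjusted p = 0.0695) passed with a pseudocount of 300, chosen after seeing the data as about the value of 1 AWF fragment. With that pseudocount 23 genes were called higher, 19 of them among the 31, and edgeR called 27 higher, 15 of them among the 31; without LSW replicate 2, edgeR called 0 genes in any contrast. Without the shallow lysate replicate 2, limma called 38 higher and 7972 lower. TPM as deposited, dominated by rRNA, gave 0 higher and 1964 lower, and quantile normalization 25 higher and 0 lower. The median log2 fold change over all genes was -2.57 with rescaled TPM, -0.85 with TPM as deposited and 0.08 after quantile normalization.

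The jasmonate and touch lists stood apart from other genes in AWF when the correlation between genes was preset, and mostly not when it was estimated. Of 21 measured jasmonate and wounding genes, LOX4 and LOX3 (7.78 ± 2.00, limma adjusted p = 0.0253) were called higher, and the jasmonate repressors JAZ12 and JAZ3, listed at 0 in AWF, were called lower. When adjusted over the list alone 3 were higher and 2 lower, and the list's median log2 fold change was 2.66. Of 22 touch and rapid-response genes, the zinc-finger factor RHL41 (7.25 ± 2.04, limma adjusted p = 0.0387) and the calmodulin-like CML38 (7.12 ± 1.91, limma adjusted p = 0.0307) were called higher and SIB1, listed at 0 in AWF, lower. Adjusted over the list alone, 5 were higher and 1 lower, and the median was 2.98. Camera with its preset correlation gave adjusted p = 3.8e-16 and 6.85e-23 for the lists, and adjusted p = 0.0557 and 0.0914 with an estimated correlation. With an estimated correlation the adjusted p was 0.0106 for both with a pseudocount of 300, 0.0938 for both with the replicate as a block (a block in doubt for AWF, whose files carry other replicate numbers), 0.106 and 0.128 with a pseudocount of 0.1 and 0.527 for both after quantile normalization. Over the alternatives with the preset correlation it ranged from 6.15e-22 to 0.0025 for the jasmonate list and from 2.28e-31 to 1.75e-05 for the touch list. Fry, which tests whether members move one way on balance, gave adjusted p = 0.556 and 0.224, and 0.0458 and 0.0394 after quantile normalization. On TPM as deposited the medians turned to -1.40 and -1.004, while quantile normalization gave 3.02 and 3.42. EdgeR tested 13 and 16 members and called 4 higher and 0 lower in the jasmonate list (LOX4, LOX3, JAZ1 and OPR3) and 2 higher and 0 lower in the touch list (BAP1 and CML38). These calls lay just under the threshold (edgeR adjusted p from 0.0453 to 0.0494) and depend on LSW replicate 2, as given above. Of these, JAZ1 (log2 fold change 3.22, edgeR adjusted p = 0.0453), OPR3 (3.09, 0.0453; 2227 rescaled TPM in AWF and 53.7 in not ribodepleted lysate) and BAP1 (4.19, edgeR adjusted p = 0.0454) were not called by limma. Members with high AWF values that neither test called, picked after their values were seen, included AOS, which makes allene oxide (3664 ± 1755 rescaled TPM in AWF and 414 in not ribodepleted lysate). TCH3 (2968 ± 401 and 612), STZ (2668 and 127) and WRKY40 (2265 and 42.8) of the touch list were likewise not called by either.

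As shares of nuclear mRNA, a summary chosen after the data were seen, the jasmonate list held 2.57% ± 0.894 (SD, n = 3) in AWF, 0.274% ± 0.147 in not ribodepleted lysate and 0.332% in LSW replicate 1. The touch list held 2.00% ± 0.662, 0.293% ± 0.0782 and 0.363%. Together they held 4.56% ± 1.502 in AWF, 8.05-fold the 0.567% ± 0.130 of the lysate, and the lowest AWF library (2.99%) lay above the highest lysate library (0.717%; exact permutation p = 0.1, adjusted 0.16, n = 3 against 3). Markers of guard cells and trichomes were listed at 0 in AWF, and the epidermis, guard cell, trichome and vascular lists together held 0.124% ± 0.118 in AWF, 0.421% ± 0.0793 in not ribodepleted lysate and 0.467% in LSW replicate 1. Reference genes held 1.32% ± 0.0881 in AWF, 0.557% ± 0.113 in that lysate and 1.29% in LSW replicate 1.

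**Figure D2:**
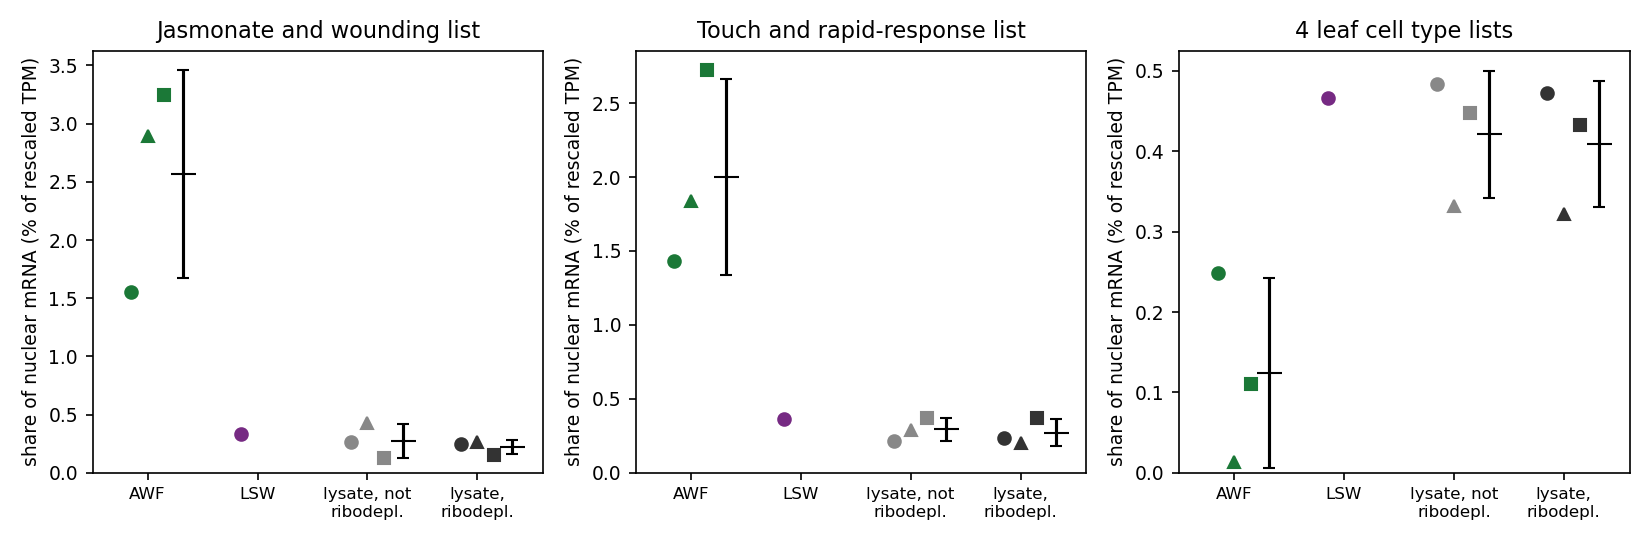
Share of nuclear mRNA (% of rescaled TPM) held by the jasmonate and wounding list, the touch and rapid-response list and the 4 leaf cell type lists together, per library; circles, triangles and squares are replicates 1, 2 and 3, black bars are means ± SD of 3 libraries, and only LSW replicate 1 is drawn for LSW. The first 2 lists average 2.57% and 2.00% in AWF and 0.274% and 0.293% in not ribodepleted lysate.

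The photosynthetic mRNAs that dominate a leaf were also the most abundant in AWF. CAB1, a light-harvesting protein of photosystem II, averaged 38458 ± 12388 rescaled TPM (SD, n = 3) in AWF, 32498 ± 5017 in not ribodepleted lysate and 17743 in LSW replicate 1. LHB1B2 averaged 16347, 14783 and 8265, and the Rubisco small subunit gene RBCS1A 9202, 7257 and 5752. These genes belong to near-identical families whose members share reads, so single values are uncertain. The light-harvesting and photosystem list held 13.4% ± 2.45 of nuclear mRNA in AWF and 16.4% ± 4.75 in not ribodepleted lysate, and the Calvin cycle list 2.96% and 2.59%. Of 47 light-harvesting and photosystem genes 0 were called higher by limma and 5 lower, among them PSAN, PETC, PSAH2 and PETE1, with the same 0 and 5 when adjusted over the list alone. The median log2 fold change was -0.998 and the mean -2.80, yet camera, which compares a list with all other genes, gave Up with adjusted p = 0.00436 (adjusted p = 0.989 with an estimated correlation). After quantile normalization it turned to Down with adjusted p = 1.03e-08, though with an estimated correlation 0 lists were called in that setting. EdgeR called 0 of 45 tested members higher and 15 lower, such as LHB1B1 (log2 fold change -2.91, edgeR adjusted p = 0.0458) and PSBY (-4.87, edgeR adjusted p = 0.0453). Against random lists matched for level, added after the data were seen, the median with a pseudocount of 300 was -0.70, at percentile 0 (95% range -0.14 to 0.56). Single members were thus called lower in AWF by edgeR and limma, but these calls were weak. The edgeR calls had edgeR adjusted p from 0.0453 to 0.04996. Limma called 1806 genes lower in counts simulated at these depths with no gene changed. In the real data, with all libraries kept, it called 0 genes lower with a pseudocount of 300 or after quantile normalization. The sign for the list as a whole changed with the scaling, and its summed shares overlapped between fractions (exact permutation p = 0.4, n = 3).

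Most genes called lower in AWF were below what its depth could show. Of the 2004, 2003 were listed at 0 in all 3 AWF libraries, and at the lysate level the median gene would have had 0.8726 fragments over the AWF libraries together. In counts simulated at these depths with no gene changed, limma called 1806 genes lower and 1 higher among 15570, and with a pseudocount of 300 it called 0 lower and 1 higher. The 8 lowest by the fixed rule, listed at 0 in every AWF library, were AT1G56220, GSTF9, PSAN, AT2G15960, NIT1, AT1G23130, AT3G41762 and ESM1, with 1096 to 2428 rescaled TPM in not ribodepleted lysate and limma adjusted p from 0.00238 to 0.0142. EdgeR also called all 8, each just under the threshold (edgeR adjusted p = 0.0453). The pseudocount of 300, which found 1 of 100 simulated genes raised 16-fold, ended all 8 calls. Without the shallow lysate replicate 2, that pseudocount gave many more calls in this contrast, as given below under processing. Just 10 of the 2004 had an expectation of at least 10 fragments, and all 10 were observed at 0. They include ESM1 (12.1 expected), NIT1 (13.2) and GSTF9 (10.8), which act in glucosinolate breakdown, nitrile hydrolysis and glutathione conjugation, the carbonic anhydrase CA1 (10.2) and SEN1 (12.8). Genes of other lists called lower were all listed at 0 in AWF: 10 of 25 cytosolic ribosomal protein genes (AT3G09200, SAC52, STV1 and RPS15A among them; 12 adjusted over the list alone). Also lower were 4 of 21 Calvin cycle genes (RPE, GAPA-2, HCEF1 and EMB3119; 4 adjusted over the list alone), 3 of 26 epidermis genes (CYP86A2, KCS10 and ABCG12; 4 over the list alone) and 3 of 14 vascular genes (SWEET11, PP2-A1 and SWEET12; 3 over the list alone). So were 2 each of 17 salicylate and immune genes (PR5, WAK1), 14 circadian genes (PRR7, GI) and 12 reference genes (GAPC1, PP2AA3), and TGG1 of 8 guard cell genes and AT5G06700 of 7 trichome genes, with the same numbers over the list alone. Fry put the trichome (adjusted p = 0.0485) and vascular (0.0426) lists lower on balance, but it does not take off the median of -2.57 over all genes, and after quantile normalization its adjusted p was 0.879 and 0.356. Of 3 measured pollen genes limma called 0 over all genes and 0 over the list alone, and 0 of the root markers passed the filter.

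Against ribodepleted lysate, limma called 58 genes higher in AWF and 10540 lower, with a median log2 fold change of -3.83; quantile normalization gave 1577 higher and 460 lower, and a pseudocount of 300 109 higher, 50 of them among the 58, and 1609 lower. LOX4 was again among those called higher (log2 fold change 8.57, limma adjusted p = 0.00544). Of the lower calls, 10517 were listed at 0 in all AWF libraries, with a median expectation of 0.266 fragments.

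For LSW against not ribodepleted lysate, nearly all genes called lower were listed at 0 in the LSW libraries, most of them below what LSW replicate 1 could show. The genes named by the fixed rule included the linker histone HIS1-3 (902 ± 973 rescaled TPM in lysate, SD, n = 3), with 34.4 LSW fragments expected, 9.85 of them in LSW replicate 1. The tonoplast aquaporin DELTA-TIP had 960.4 ± 1278 (50.03 expected, 14.3 in replicate 1) and the iron store FER1 438 ± 170 (29.9 and 8.56). The vacuolar transporter CAX1 (379.8 ± 264; 35.4 and 10.1) and the vacuolar proton pump AVP1 (334 ± 108; 43.1 and 12.3) were also called, and limma adjusted p over the named genes ran from 0.00628 to 0.0454. The fixed rule also named AT1G49750, AT5G65220 and PSB29 on this side. The only gene called higher, AT3G22410 (chromosome 3, 7933167 to 7935808; log2 fold change 5.01 ± 0.78, limma adjusted p = 0.00628), rested on 2 fragments. Limma called 1 gene higher and 1206 lower, of which 1203 were listed at 0 in both LSW libraries, with a median expectation of 4.74 fragments, under 3 for 274 genes. That expectation takes in LSW replicate 2, whose mRNA value fell mostly on insertion genes; in LSW replicate 1 alone the median was 1.36 fragments, with 1089 genes under 3 and 6 at 10 or more. None of these calls stood with edgeR (0 calls) or a pseudocount of 300 (0 calls), quantile normalization gave 0 and TPM as deposited 223. Limma called 5981 without lysate replicate 2 and 2051 without LSW replicate 1, and 4387 genes had an unadjusted limma p under 0.05.

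By list, limma called lower in LSW 3 of 21 jasmonate genes (JAZ12, AOC1, JAZ3), 2 of 25 ribosomal protein genes (AT5G27700, RPS5B), 2 of 14 vascular genes (SWEET11, SWEET12), 2 of 17 salicylate and immune genes (PR5, WAK1), 1 of 7 trichome genes (AT5G06700) and 1 of 12 reference genes (PP2AA3). These numbers were the same when adjusted over the list alone, and 0 genes of the other lists were called. Camera called 0 lists with rescaled TPM. After quantile normalization it called light harvesting (adjusted p = 1.04e-06), Calvin cycle (0.00229), ribosomal protein (0.00396) and reference genes (0.0404) lower. With a pseudocount of 300 it called light harvesting lower (0.00494) and the touch (0.0375) and ribosomal protein (0.0473) lists higher than other genes. With an estimated correlation it called 0 in each of these settings. Fry gave the vascular list as lower (adjusted p = 0.0485), and 0.412 after quantile normalization. All these list tests include LSW replicate 2, with 0.279% of nuclear mRNA on the light-harvesting list and 0 on the vascular list. As a single library, LSW replicate 1 held 1.03% of nuclear mRNA on the ribosomal protein list, against 0.475% ± 0.177 in not ribodepleted lysate and 0.355% ± 0.130 in AWF (SD, n = 3), and 10.2% on the light-harvesting list, against 16.4% and 13.4%. Against ribodepleted lysate limma called 2 genes higher and 7718 lower in LSW, 859 higher and 91 lower after quantile normalization, 1 and 218 with a pseudocount of 300 and 0 with edgeR. Without ribodepleted replicates 3 and 1 the totals were 0 and 729, and without LSW replicates 1 and 2 they were 2650 and 1502.

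Between LSW and AWF, a contrast that uses the same AWF libraries again, camera called 4 lists with the preset correlation and 0 with an estimated one (5 and 2 with a pseudocount of 300). It called the jasmonate list lower in LSW (adjusted p = 8.26e-17, or adjusted p = 0.0557 with an estimated correlation; median log2 fold change -5.47) and the touch list lower (3.14e-21, or adjusted p = 0.0914 with an estimated correlation; median -5.25). By limma 6 and 7 members were lower when adjusted over the list alone, and 0 over all genes. LOX4 was listed at 0 in LSW replicate 1, AOS had 336 rescaled TPM there against 3664 in AWF, and STZ 392 against 2668. The light-harvesting list was called lower (adjusted p = 2.88e-05; adjusted p = 0.989 with an estimated correlation) but turned to Up with adjusted p = 0.121 after quantile normalization. The ribosomal protein list was called higher (median 3.87, adjusted p = 0.00205; adjusted p = 0.989 with an estimated correlation). These list tests include LSW replicate 2, whose mRNA value fell mostly on insertion genes. It held 0.279% of nuclear mRNA on the light-harvesting list and 0 on the jasmonate, touch and ribosomal protein lists. The medians and calls rest in part on that library, and camera was not run without it. EdgeR called 7 single genes higher, all insertion genes, whose reads cannot be told from mitochondrial RNA. Over single genes limma called 0 of 15504, with 344 at an unadjusted p under 0.05. The count was 196 without LSW replicate 1, and 1588 (1555 higher) without LSW replicate 2, which leaves a single LSW library.

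The lysates differed in their share of nuclear mRNA, while calls of single genes between them did not stand across settings. The ribodepleted lysate held 3.10-fold more nuclear mRNA by TPM share than the not ribodepleted lysate (exact permutation p = 0.1, adjusted 0.1125, n = 3 against 3) and 10.5-fold more by covered bases (exact permutation p = 0.1, adjusted 0.108). Limma called 675 genes higher in the ribodepleted lysate and 0 lower (28 lower at an unadjusted p under 0.05), with a median log2 fold change of 1.1603; quantile normalization gave 1 higher and 22 lower, and edgeR 0. Same-numbered lysate libraries deviated together, and the lysates fitted alone with the replicate as a block gave 10 calls, 1 higher and 9 lower. The count was 0 without any 1 ribodepleted library, 2288 without not ribodepleted replicate 1 and 1150 without not ribodepleted replicate 3.

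The mRNA fold changes of LSW and AWF against not ribodepleted lysate correlated at 0.559 across genes, which are not independent replicates, with a covariance of 2.27. Unchanged groups simulated against the same lysate gave 0.448 and a covariance of 1.28, a difference in covariance of 0.991. With no lysate library shared, r was 0.324 and 0.355, against simulated values of -0.000912 and 0.00349. Same-numbered lysates deviate together (0.265 to 0.517) and the simulation treats them as independent, so these simulated values are too low a reference and the crossed r is not free of the shared lysate. Calls lower in both numbered 1196, against 156 for independent lists, and calls higher in both numbered 0; since nearly all lower calls were listed at 0, both comparisons share the same limit of depth.

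The small RNA libraries gave replicated profiles of lysate and LSW, and less so of AWF. Across miRNAs, lysate libraries correlated at 0.962 to 0.971 with each other, LSW libraries at 0.859 to 0.944 and AWF libraries at 0.787 to 0.814, while pairs of AWF with LSW ranged from 0.702 to 0.865. AWF replicate 1 correlated at 0.824 to 0.865 with the LSW libraries and at 0.795 and 0.787 with AWF replicates 2 and 3. The growth regulator miR396a-5p was the most abundant miRNA in AWF and lysate, at 20.7% ± 9.48 (SD, n = 3) and 17.3% ± 4.196 of counts, and held 5.33% ± 1.62 in LSW. LSW was led by miR167a-3p (12.2% ± 5.62) and by miR398b-5p and its identical copy miR398c-5p (8.80% ± 2.39, against 0.805% ± 0.444 in lysate); miR167a-3p held 23.4%, 0.459% and 0.428% in the 3 AWF libraries. The miR166 group, which targets class III homeodomain-leucine zipper genes, held 8.35% ± 2.15 in AWF, 5.78% ± 2.34 in LSW and 14.2% ± 3.75 in lysate, and miR159a, which targets MYB transcription factors, 8.63% ± 4.915, 1.96% ± 1.14 and 7.37% ± 1.71. In lysate miR396b-5p held 8.84% ± 2.96. AWF libraries held a mean of 123 ± 34.1 miRNAs, LSW 176 ± 44.7 and lysate 236 ± 16.01 (LSW against AWF exact permutation p = 0.2, n = 3). Thinned to 6967 counts, the means were 101.3 ± 3.51, 112 ± 2.81 and 104 ± 4.86. At this depth AWF libraries (97.9 to 104.9) overlapped lysate libraries (98.9 to 109; exact permutation p = 0.5, n = 3), and LSW held 10.6 more than AWF (exact permutation p = 0.1, adjusted 0.15).

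LSW and AWF held different miRNAs, with the limit that AWF replicate 1, which holds most AWF counts, was closer to LSW than to the other AWF libraries. Several hairpin arms abundant enough to count in LSW had no count in AWF. MiR390b-3p (276 counts over the LSW libraries) was, by its pooled level, at least 11.8-fold higher in LSW (edgeR adjusted p = 0.00816). The bound was for miR158a-5p at least 8.78-fold (0.00716), miR160a-3p at least 6.05-fold (0.0121) and miR173-3p at least 4.09-fold (0.0391), each against a limit of 3 counts over the AWF group. These bounds rest on AWF replicate 1: without it they fall to 2.16-fold, 1.61-fold and 1.11-fold for miR390b-3p, miR158a-5p and miR160a-3p, and for miR173-3p no bound is left (0.751). MiR169a-3p averaged 1883 ± 859 TMM-scaled CPM in LSW and 115 ± 63.6 in AWF (log2 fold change 4.47 ± 1.17, edgeR adjusted p = 0.00613). MiR156c-3p averaged 5878 ± 3902 and 232 ± 401 (4.19 ± 1.12, edgeR adjusted p = 0.00671), with all 43 AWF counts in replicate 1. Its log2 fold change was 3.55 without AWF replicate 2 and 14.39 without AWF replicate 1, where AWF is at 0 and the counts allow a bound of at least 35.2-fold. On the AWF side stood miR2933a,b (log2 fold change -5.65 ± 1.39), miR4228-3p (-4.99 ± 1.27), miR2936 (-4.76 ± 1.07, with 71.6 ± 83.4 in LSW and 2197 ± 1720 in AWF), miR5659 (-4.55 ± 1.09), miR8166 (-4.50 ± 1.04) and the MYB regulator miR858a (-4.01 ± 1.05), with edgeR adjusted p from 0.00388 to 0.00613. The first of these rest on few counts. MiR2933a,b had 6, 4 and 4 in AWF and 1, 3 and 0 in LSW, and miR4228-3p 3, 7 and 6 and 0, 8 and 1.

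EdgeR called 16 miRNAs higher and 16 lower in LSW than in AWF among 142 tested. With DESeq2 size factors 22 were higher and 16 lower, and with library size alone 24 and 12; the median log2 fold change moved from 0.35 with TMM to 0.61 and 0.89. All 12 named miRNAs kept their direction under each setting and left-out library that could test them. Without AWF replicate 1, by far the deepest AWF library, the calls of miR390b-3p, miR158a-5p, miR160a-3p and miR173-3p were lost (edgeR adjusted p = 0.0781, 0.103, 0.162 and 0.285), though 52 miRNAs were called in all. In turn 20 were called without AWF replicate 3 and 17 without LSW replicate 2, which also ended the call of miR858a (edgeR adjusted p = 0.0517). MiR173-3p was also lost with the replicate as a block and without any 1 of AWF replicates 2 and 3 and LSW replicates 1 and 2.

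**Figure D3:**
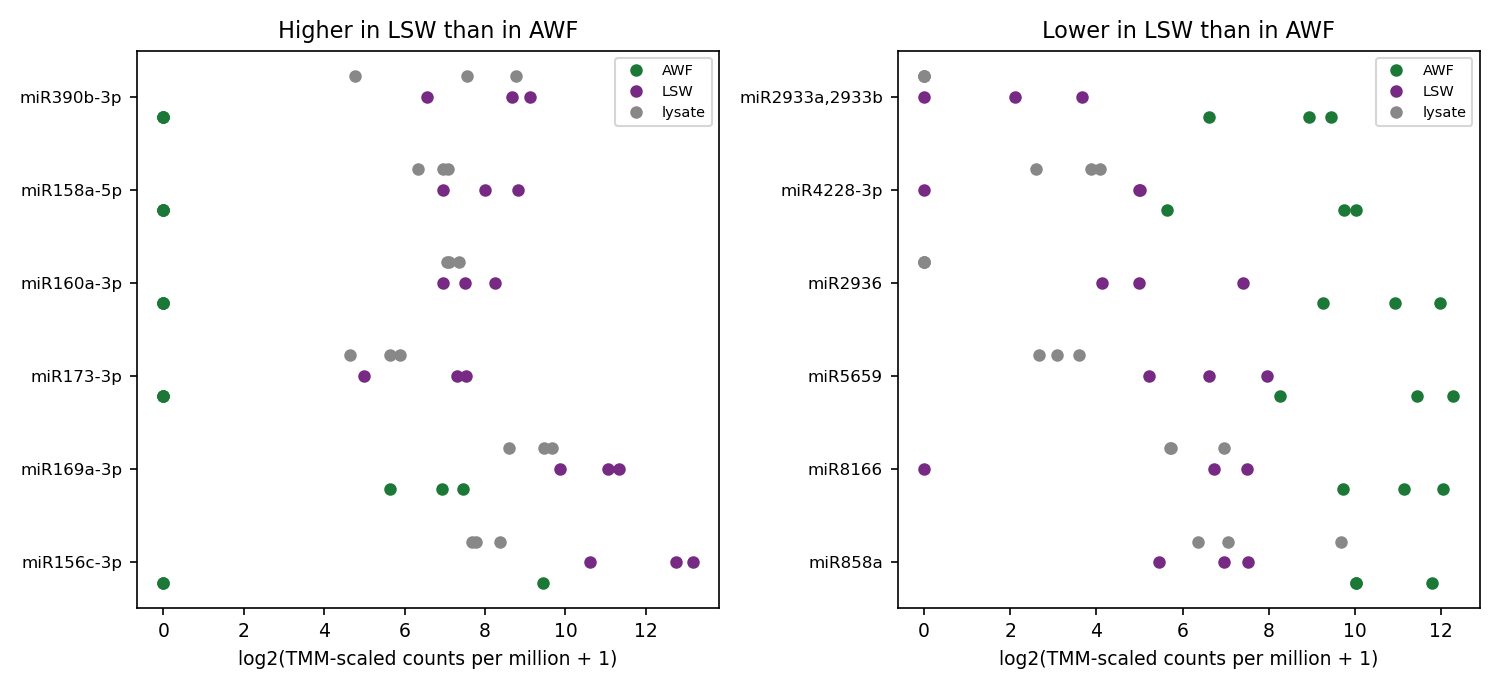
log2 of TMM-scaled CPM plus 1 for the 12 miRNAs named as higher or lower in LSW than in AWF; each point is 1 library of AWF, LSW or lysate (3 each, some overlapping), and 0 is a count of 0. MiR390b-3p, miR158a-5p, miR160a-3p and miR173-3p sit at 0 in all AWF libraries, and miR2933a,b and miR2936 sit at 0 in all lysate libraries.

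Against lysate, the miRNAs with the largest rise in LSW were ones that lysate barely held, which naming by fold favours. MiR8176 and miR2936 had no count in lysate. By their pooled levels they were at least 302.9-fold and at least 80.2-fold higher in LSW (edgeR adjusted p = 5.24e-07 and 3.44e-05, limit of 3 counts over the lysate group). Their counts in LSW replicates 1, 2 and 3 were 43, 132 and 10, and 5, 43 and 1, so single libraries may lie below these folds. MiR156a-3p averaged 591 ± 181 TMM-scaled CPM in LSW and 3.96 ± 2.54 in lysate (log2 fold change 7.07 ± 1.04, edgeR adjusted p = 2.76e-06), and miR169b-5p,c rose by 6.94 ± 1.14 (1.71e-05). The group miR169d,e,f-5p,g-5p and miR773a each had 1 lysate count, with LSW to lysate ratios of 447 (95% counting interval 78.2 to 17846; edgeR adjusted p = 2.21e-05) and 157 (26.3 to 6399.7; 0.000687). Lower in LSW were miR167c-5p (-4.76 ± 1.099), which targets auxin response factors, the phosphate-homeostasis miR399a (-4.47 ± 1.13), the laccase regulator miR397a (-3.96 ± 1.01), miR847 (-3.80 ± 0.93), miR846-5p (-3.77 ± 0.94) and miR846-3p (-3.75 ± 0.99), with edgeR adjusted p from 0.00116 to 0.00291. EdgeR called 27 higher and 40 lower; with DESeq2 size factors the split was 39 and 23 and with library size alone 43 and 20. The median log2 fold change moved from -0.50 to 0.26 and 0.32. The total was 42 without lysate replicate 3, 36 without LSW replicate 2 and 22 (12 higher) with all libraries thinned to 6967 counts.

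The miRNAs called higher in AWF than in lysate overlapped those of LSW, with 15 of the 21 also called in LSW. Those with the largest folds, named here, were scarce in lysate, which naming by fold favours. Others were not: miR167d, higher in both washes, averaged 2087 TMM-scaled CPM in lysate. By pooled levels, miR2936 was at least 985.8-fold, miR8176 at least 1408-fold and miR2933a,b at least 179-fold higher in AWF, with no count in lysate (edgeR adjusted p = 3.93e-08, 3.36e-08 and 2.96e-06). Their counts in AWF replicates 1, 2 and 3 were 38, 16 and 23, then 100, 6 and 4, then 6, 4 and 4 (14 in all for miR2933a,b). Single libraries may lie below these folds. MiR5659 averaged 2702 ± 2347 TMM-scaled CPM in AWF and 8.01 ± 2.91 in lysate (log2 fold change 8.32 ± 1.25, edgeR adjusted p = 2.82e-06), miR8167a-f 5773 ± 3422 and 20.3 ± 6.0005 (8.12 ± 1.25, 2.96e-06) and miR5653 9072 ± 5519 and 88.1 ± 34.1 (6.67 ± 1.13, 1.55e-05). MiR5996, miR167c-5p, miR390b-3p, miR160a-3p, miR164b-3p and miR781a,b had no count in AWF and were at least 7.07-fold, 7.72-fold, 6.41-fold, 3.59-fold, 3.07-fold and 2.97-fold lower (edgeR adjusted p from 0.00591 to 0.034). All 6 of these lower calls were lost without AWF replicate 1, with edgeR adjusted p from 0.148 to 0.337, where the bounds fall to 1.2985-fold, 1.42-fold and 1.18-fold for the first 3 and none is left for the others (0.660, 0.564 and 0.545). MiR164b-3p was also lost with DESeq2 size factors, with library size alone and without AWF replicate 2, lysate replicate 1 or LSW replicate 3. MiR781a,b was also lost with the replicate as a block and without AWF replicate 2, and miR390b-3p without lysate replicate 3. EdgeR called 21 higher and 28 lower, DESeq2 size factors gave 25 and 21, library size alone 24 and 23, and thinning to 6967 counts 9 and 6; the median log2 fold change was -0.75, -0.24 and -0.46 under the 3 scalings.

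By miRNA list, the Brassicaceae young miRNAs, known mostly from this plant family, were the one group whose members moved one way on balance with TMM scaling. Of 15 tested, 0 were called higher and 8 lower in LSW than in lysate by edgeR (median log2 fold change -2.05; fry adjusted p = 0.0169), such as miR846-5p, miR846-3p, miR823 (-3.01 ± 0.95) and miR391-3p (-2.98 ± 0.93). With DESeq2 size factors 3 were higher and 5 lower (fry adjusted p = 0.0652) and with library size alone 3 and 4 (0.235). MiR163 of that list went the other way in AWF, with 51622 TMM-scaled CPM against 908 in lysate (5.83 ± 1.03, edgeR adjusted p = 2.9e-05). Over the list alone 1 was called higher and 8 lower in LSW against lysate, 2 higher and 6 lower in AWF against lysate (2 and 5 over all miRNAs) and 1 and 3 in LSW against AWF on both counts.

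The other lists moved in both directions. Of 8 copper-regulated miRNAs, which silence copper proteins, 2 were higher and 0 lower in LSW than in AWF (miR398a-3p 2.94 ± 0.92, edgeR adjusted p = 0.0199; miR398b-3p,c-3p 2.82 ± 0.90, 0.0212). They were 2 higher and 2 lower in LSW than in lysate, and 0 and 2 in AWF against lysate (0 and 0 when adjusted over the list alone, the first 2 contrasts unchanged). Of 13 auxin pathway miRNAs, 3 were higher and 0 lower, 3 and 2, and 1 and 5 in those contrasts (3 and 0, 2 and 2, 2 and 5 over the list alone). MiR167d was higher in both washes, by 3.61 ± 0.81 in LSW (edgeR adjusted p = 0.000776) and 3.61 ± 0.81 in AWF (0.000829). Of 45 growth and phase miRNAs, 7 and 4, 9 and 10, and 5 and 10 were called (8 and 4, 9 and 10, 5 and 10 over the list alone). Of 7 miRNAs of the small RNA pathway 2 and 0, 0 and 2, and 0 and 1 were called (2 and 0, 0 and 0, 0 and 1 over the list alone). Of 9 that trigger secondary siRNAs the numbers were 1 and 0, 1 and 3, and 0 and 1 (0 and 0, 1 and 3, 0 and 1), and of 6 for phosphate and sulfate 0 and 0, 1 and 2, and 0 and 0 on both counts. The fry adjusted p of these lists ranged upward from 0.0765 with TMM. With DESeq2 size factors it was 0.0137 for the auxin list and 0.0107 for the small RNA pathway list in LSW against AWF, and 0.0107 for the growth list in LSW against each other fraction, where 13 and 14 members were higher and 4 and 5 lower.

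The washes shared part of their difference from lysate. Of miRNAs called higher than lysate, 27 in LSW and 21 in AWF, 15 were shared, against 3.99 for independent lists, and of those called lower, 40 and 28, 15 were shared, against 7.89. The fold changes correlated at 0.541 across the 142 miRNAs with a covariance of 4.16. Unchanged groups simulated against the same lysate gave 0.355 and 0.389, a difference in covariance of 3.77. Part of the excess overlap may come from the shared lysate libraries. Part may also come from AWF replicate 1, which holds most AWF counts. Its mean r was 0.847 with LSW and 0.791 with the other AWF libraries. The overlap and correlation were not computed without it.

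The arms of miRNA hairpins were divided differently in LSW, a comparison chosen after the data were seen. A miRNA hairpin yields a strand from each arm, and the strand with fewer lysate counts is here the minor arm. Over 43 hairpin groups, minor arms held 31.1%, 38.2% and 43.6% of counts in the LSW libraries (mean 37.6% ± 6.25, SD, n = 3), 12.05% ± 1.297 in lysate and 16.03% ± 6.69 in AWF. All LSW libraries lay above all lysate and all AWF libraries (exact permutation p = 0.1, n = 3, for each), while the AWF libraries (22.2%, 16.9% and 8.94%) overlapped those of lysate (13.5%, 11.1% and 11.6%; exact permutation p = 0.4, n = 3). For miR396a the 3p arm held 31.8%, 45.8% and 65.4% of the hairpin's counts in LSW and 9.60%, 5.16% and 8.74% in lysate, and for the miR156 group, whose 5p sequences are merged, the 3p arms together held 46.6%, 50.4% and 48.0% against 4.199%, 8.14% and 6.97%. The share was higher in LSW than in lysate for 29 of 39 hairpins that could be compared (74.4%, exact 95% binomial interval 57.9 to 87.0), and in AWF for 15 of 27. An arm chosen as minor in lysate has more room to rise than to fall, and hairpins are not independent replicates. The interval therefore does not measure a shift free of that choice.

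**Figure D4:**
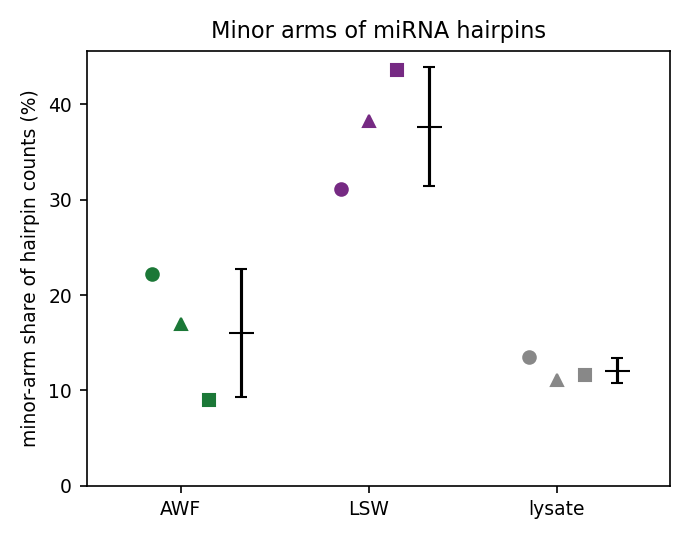
Share of hairpin counts (%) on the minor arm, chosen by lysate counts, in each small RNA library; circles, triangles and squares are replicates 1, 2 and 3, and black bars are means ± SD of 3 libraries. LSW libraries lie between 31.1% and 43.6%, above every AWF and lysate library.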

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

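The test of an exchange of labels was chosen after the result was seen, and the others below had their outcomes written down before they were run.

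A difference between groups set apart 15 miRNAs: each was called in LSW against AWF and lay on opposite sides of lysate in the washes, 11 above lysate in LSW and below it in AWF, and 4 the reverse. The difference itself is what LSW against AWF tests, and 0 of the 15 were called against lysate in both washes. The copies miR172b-5p,e-5p, from hairpins of the miR172 family, were at 0.11 in LSW and -2.81 in AWF on the log2 scale (LSW against AWF 2.93, edgeR adjusted p = 0.0239). MiR398b-3p,c-3p, which lower copper enzymes, were at 0.60 and -2.22. On the other side, miR159b-3p was at -2.42 in LSW and 0.45 in AWF (LSW against AWF -2.87, edgeR adjusted p = 0.00531) and miR858a at -1.58 and 2.43. With DESeq2 size factors 20 of 38 called miRNAs lay on opposite sides, and with library size alone 20 of 36. Both are relative measures, so a scaling error would shift all miRNAs of a wash together.

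Small RNA of AWF replicate 1 resembled LSW more than the other AWF libraries, with a mean r of 0.847 with LSW and 0.791 with AWF replicates 2 and 3. An exchange with a LSW library is argued against, because each LSW library was closer to its own group than to AWF replicates 2 and 3 by at least 0.158. Depth stays open: thinned to the smallest library, the difference fell as low as -0.00556, though 2 of 100 draws were at or under 0 and the median was 0.0303. A mixture of both kinds of RNA also stays open. For 94% (47 of 50) of miRNAs at least 4-fold apart, AWF replicate 1 lay between the LSW mean and the mean of AWF replicates 2 and 3. Both means were widened by the range of their libraries. That lets values outside the means pass, so the share does not show that AWF replicate 1 is a mixture. A single wrong label without a partner was not excluded, and no biological explanation was tested.

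Other splits of the same 6 libraries are too few (10) for a share under 0.05. For miRNAs, the real split gave 32 calls in LSW against AWF and the highest other split 3, with 1 split as large. LSW against lysate gave 67 and 0, and AWF against lysate 49 and 0, again with 1 split as large in each. For mRNA, AWF against not ribodepleted lysate gave 2035 and 0, and AWF against ribodepleted lysate 10598 and 0, with 1 split as large in each. The lysate pair gave 675 and another split 814, so 2 of the 10 splits were as large; with the replicate block, which respects the pairing of lysates by number, the fit of all groups gave 637 and the lysates alone 10.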

How the results depend on the processing

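The tests added after the result was seen are those with a pseudocount of 300, with AT2G01021 kept, without insertion genes, with LSW replicate 1 as the lone LSW library, without the shallow lysate combined with a pseudocount, with thinned fragments, with an estimated correlation combined with another change, and of the lysates alone with the block. The cause of the changes below was not tested unless stated.

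RNA class shares moved by more than the spread in 5 of 6 cases as covered bases (shares of FPKM equal those of TPM by construction and test nothing) and in 0 of 36 fits without 1 library. All kept their direction but rRNA in AWF minus ribodepleted lysate. As shares of covered bases, which do not divide by length, AWF minus not ribodepleted lysate was -2.87 percentage points for mRNA and -0.0441 for small nuclear RNA, AWF minus ribodepleted lysate -30.5 and the lysate pair 27.6 for mRNA, and rRNA in AWF minus ribodepleted lysate turned from -1.53 to 32.7. Thinned to 1 depth, AWF held -509 genes relative to not ribodepleted and -595.6 relative to ribodepleted lysate, and the lysates differed by 86.6. With a minimum of 10 rescaled TPM the AWF to ribodepleted difference was -9676. Thinned miRNA numbers gave LSW minus lysate 8.04, a change of sign, and AWF minus lysate -2.56, so most of the AWF gap came from depth.

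Gene list tests kept direction and side in 29 of 63 alternatives; 30 lost the call and 4 reversed. With an estimated correlation the adjusted p was 0.0557 for jasmonate and 0.0914 for touch, in both LSW against AWF and AWF against lysate, and 0.989 for light harvesting in both and for ribosomal proteins in LSW against AWF. Together with an estimated correlation, a pseudocount of 0.1 gave 0.106 for jasmonate and 0.128 for touch in both contrasts, and the replicate block, in doubt for AWF, whose RNA-seq files carry other replicate numbers, gave 0.0938 for both lists in both contrasts. Quantile normalization gave 0.0885 for both in LSW against AWF and 0.527 for both in AWF against lysate. For light harvesting in both contrasts and ribosomal proteins in LSW against AWF, a pseudocount of 0.1 gave 0.946 and the block 0.962. A pseudocount of 300 gave 0.934 for light harvesting and ribosomal proteins in LSW against AWF and 0.960 for light harvesting in AWF against lysate, which a pseudocount of 300 alone put at 0.256. After quantile normalization the light-harvesting direction reversed in both contrasts (0.121 and 1.03e-08; with an estimated correlation 0.650 and 0.527), and ribosomal proteins in LSW against AWF gave 0.527 with it.

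Counts of called genes stayed within 1.5 times in 58 of 100 alternatives. In the order LSW against AWF, LSW, then AWF, against not ribodepleted lysate, LSW, then AWF, against ribodepleted lysate, and the lysate pair, quantile normalization gave 6, 0, 25, 950, 2037 and 23 and edgeR 7, 0, 254, 0, 467 and 0. With LSW replicate 1 as the lone LSW library edgeR gave 0 in all 6, with more genes tested. A pseudocount of 300 gave 0, 23, 219, 1718 and 348 for the last 5, and with the lone LSW library 1677 in LSW against AWF, then 29 in AWF against not ribodepleted lysate, 1058, 1703 and 188. A pseudocount of 300 without the shallow lysate gave 3524 in AWF against not ribodepleted lysate and 281 in the lysate pair. TPM as deposited gave 223 in LSW against not ribodepleted lysate, 6863 in AWF against ribodepleted lysate and 4201 in the lysate pair. For LSW against AWF a pseudocount of 0.1 gave 11, a pseudocount of 5 gave 5, the stricter filter 4 and leaving out insertion genes 13. A pseudocount of 5 gave 726 in LSW against not ribodepleted lysate. With AT2G01021 kept, LSW against ribodepleted lysate gave 13588 and the lysate pair 11596, since that gene takes a different share of each library. The lysate pair gave 101 with the stricter filter, 0 as the only groups fitted, and 10 alone with the replicate block, which allows for the pairing.

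Leaving out 1 library gave 0 to 1588 calls in LSW against AWF (1588 without LSW replicate 2), 1062 to 5981 in LSW against not ribodepleted lysate, 1442 to 8010 in AWF against it (both maxima without lysate replicate 2), 0 to 5976 and 7845 to 9893 in LSW and AWF against ribodepleted lysate, and 0 to 2288 in the lysate pair (0 without any 1 ribodepleted library, 2288 without not ribodepleted replicate 1). A lone LSW library is assumed to vary like the other groups. Class share differences ranged from -2.42 to -1.66 and from -7.35 to -5.81 for mRNA in AWF against the lysates, 3.76 to 5.30 in the lysate pair, 2.74 to 6.47 and -3.33 to 0.398 for rRNA in AWF against the lysates and -0.230 to -0.197 for small nuclear RNA.

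Calls of miRNAs stayed within 1.5 times in 19 of 21 alternatives. Thinned to 6967 counts, LSW against lysate gave 22 and AWF against lysate 15, with 62 miRNAs tested. Leaving out 1 library gave 17 to 52 in LSW against AWF, 36 to 68 in LSW against lysate and 39 to 53 in AWF against lysate. Named miRNAs kept direction and side in 140 of 144 alternatives and 290 of 310 fits without 1 library, and named genes in 23 of 49. The mRNA fold changes of LSW and AWF correlated at 0.324 and 0.355 with crossed lysates and at 0.273 with a pseudocount of 300 as well, against 0.559, which the shared lysate raised in simulation; same-numbered lysates deviate together, so the crossed values may still be raised.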

Other observations

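The minor-arm shares, list shares, matched random lists, pseudocount of 300 and estimated correlation combined with another change below were chosen after the data were seen. The tests of cell type shares and fragments were chosen after their values were seen, and the outcomes of the other tests were written down before they were run.

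Minor arms of miRNA hairpins held more of the counts in LSW (37.6% ± 6.25, SD, n = 3) than in lysate (12.05%). Examples beyond miR396a and the miR156 group were the 3p arms of the miR157 group together, with 48.4%, 52.1% and 59.9% in LSW, and miR173-3p, with 5.96%, 11.9% and 11.1% against 0.791%, 0.565% and 0.463% in lysate. MiR167a went the other way. Counting noise at low depth is argued against, since in 100 of 100 thinnings every LSW share lay above every lysate share. Thinning leaves a share unchanged on average, so it cannot decide on other effects of depth. A few abundant hairpins are argued against as the whole cause, since 74.4% of hairpins moved the same way and the lowest LSW share without the top 3 hairpin groups (21.3%) lay above the highest lysate share (13.6%). They carried part of the gap, which fell from 25.6 to 15.3 percentage points without them. Noise in the choice of arms is argued against, since with arms chosen in lysate replicate 1 the lowest LSW share was 15.5 percentage points above the highest of the other lysates. The lysate libraries are alike (r from 0.962 to 0.971), so this test cannot decide on another effect of choosing arms in lysate. Arm use that departs from lysate in random directions could also raise the minor-arm share. The cause was not tested. Differences in strand stability or in library ligation between fractions stay open.

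As lists, jasmonate and touch genes stood above other genes in AWF with the preset correlation, but with an estimated correlation the adjusted p was 0.0557 and 0.0914, 0.106 and 0.128 with a pseudocount of 0.1, 0.527 for both after quantile normalization and 0.0106 for both with a pseudocount of 300. By limma 2 of 21 and 2 of 22 members were called higher, and 2 and 1 lower. The depth floor is argued against as the whole cause, since with a pseudocount of 300 the median log2 fold change of the 43 measured genes was 1.11, above all 10000 matched random lists (95% range -0.20 to 0.05). A single AWF library is argued against, since the lowest median without 1 of them was 0.834, without AWF replicate 3. A higher share of the epidermis and vascular lists was not seen: together they held at most 0.248% of nuclear mRNA in an AWF library and at least 0.303% in a lysate library (difference -0.0543 percentage points). They had 13.2 fragments in AWF where 36.5 would be expected at the lysate level, and without KCS6 12.5 (upper 95% counting limit 21.6) where 30.05 would be. That limit leaves out the spread between AWF libraries, with 0.227%, 0.0134% and 0.110% on the epidermis list in replicates 1, 2 and 3. Because this test was set after its values were seen, it does not decide whether more RNA came from epidermis or vessels. More RNA from guard cells or trichomes stays open, since those lists were at 0 in AWF but, without TGG1, just 2.91 fragments would be expected. The matched lists decide nothing for the 4 cell type lists (percentile 20.3), because with 0.253 expected fragments in the median member the pseudocount holds their median near 0. Whether handling during collection raised these transcripts was not tested. The labels give no times, so the moment of collection and the fraction cannot be separated.

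Lysate replicate 1 differed from lysate replicates 2 and 3 in both library types. Circadian genes held 0.106% and 0.108% of nuclear mRNA in the not ribodepleted and ribodepleted library of replicate 1, and 0.773% to 0.996% in the others. Light-harvesting genes held 21.9% in both libraries of replicate 1 and 11.1% to 13.8% in the others. In AWF, circadian genes held 2.60% in replicate 3 and 0.209% and 0.199% in replicates 1 and 2.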
